A study of Mus musculus with 6 samples.

How the data were processed

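RNA was measured in 6 libraries of mouse embryonic stem (ES) cells of the line VGB6, 3 wild type and 3 ZRSR2 knockout. Per the labels' protocols, total RNA was extracted with RNeasy kits, polyA-selected and made into libraries with a TruSeq kit. The strand setting, the aligner, the read counter and the intron annotation are not given in the sources used here. Coordinates are those of mm10, the build named in the submitters' processing notes. Groups and replicate numbers (2, 3 and 5 in each group) were taken from the sample titles, in which the number follows a letter P that the labels do not explain. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

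Each library has 1 table of the same 219945 introns. The authors deposited 3 raw read counts per intron, named A1, A2 and Exon in the file headers, with no normalization. They also deposited a fraction named CovFrac, and a percent named MSI. The file headers do not define these names. In all 1319670 values of the 6 tables the deposited MSI percent equalled 100 × (A1 + A2) / (A1 + A2 + 2 × Exon) to within 0.01. A1 and A2 were therefore read as counts at the 2 exon-intron boundaries (summed here as unspliced reads) and Exon as the count of reads spliced across the intron. That reading comes from the formula and not from a stated definition. The deposited fraction was used only for a check of covered intron length in the closing section.

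Introns were assigned to genes by position in the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. A single gene held 196807 introns, strand decided for 9122, and 1171 lay in several genes of the same strand, of which protein-coding and then shorter genes were taken. For 11059 introns no gene and for 1786 only a gene of the other strand was found, and these had no gene name. Genes took between 99.4% and 99.5% of the spliced reads of each library. The gene count was the sum of spliced reads over the listed introns of a gene, so a gene without introns, such as Zrsr1, was not analysed here. Reads of near-identical copies and of overlapping genes may be split between them in ways the sources do not state.

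Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). CPM values of genes are spliced reads scaled to a common library size, with TMM factors. Standard errors of log2 changes were derived from the log2 change and its F statistic. Intron retention was tested with the edgeR quasi-likelihood interaction of read kind (unspliced or spliced) with genotype, with a term per sample, for introns with at least 20 reads of both kinds together in every sample. Its log2 odds is the change in the ratio of unspliced to spliced reads, knockout minus wild type. The same model compared the spliced reads of an intron with those of the other introns of its gene (usage), and with those of junctions that share 1 splice site with it (alternative junctions, at least 30 reads in all and 10 alternative reads). Gene lists with at least 3 measured genes were tested with limma 3.58.1. On log2 CPM with a prior count of 2, camera was run with a preset correlation of 0.01 and with an estimated correlation. On the gene counts, fry was run. Single values between groups were compared by two-sided exact permutation, which for 3 against 3 cannot give a p below 0.1.

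U12-type introns are defined by their splice site and branch point sequences. A genome sequence was not used here, so introns could not be classified by motif. As fixed before the data were examined for that case, introns of 30 genes known from the literature to hold a U12-type intron (recalled from memory) were compared with introns of all other genes. Most introns of such a gene are U2-type, which dilutes a change of the U12-type ones. The list was not checked for completeness, so the introns of all other genes may include U12-type ones. The design, the gene lists, the alternatives (except those said to be added) and the rule for naming genes were fixed in the same way. That rule names the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap of the groups. Of each list it names members past the threshold (at most 4), or else the 2 of highest level. Predicted genes, pseudogenes and Riken clones are counted and not named, except among the top 3. Of introns outside the U12 list it names the 5 largest rises and the 5 largest falls by the same criteria, at most 1 per gene, and of the U12 list those of 13 genes. Genes and introns named outside this rule are said to be chosen after their values were seen.

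Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors or library sizes in edgeR, other count filters and read minimums, limma on log2 ratios with 0.5 added to both counts, another reference for the intron test, a fit with the replicate number as a block, and each sample left out in turn. The closing section gives their effect. The scripts were tested on simulated data. With 16464 genes drawn from the means, library sizes and dispersions of the real libraries, the gene test recovered 39 of 98 genes changed by 1 on the log2 scale and 70 of 96 changed by 2, and called 9 unchanged genes. With 95305 introns the intron test recovered 60 of 100 changed by a log2 odds of 2 and 99 of 100 changed by 3. It called 2 unchanged introns. The changed introns were drawn only from those with at least 10 unspliced reads, as 65194 of the 95371 tested introns have. Recovery among introns with fewer was not simulated. A simulated list of 15 genes moved by 0.6 gave a camera p of 8.12e-08, and 0 of 20 unchanged lists were called. Simulated genes varied independently, whereas real lists had estimated correlations of up to 0.73. False calls of lists with correlated genes were therefore not tested. The simulated spread of introns was a dispersion set to 0.025 for all and not estimated from the libraries. False calls of introns at their real spread were therefore not tested.

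Spliced reads per library ranged from 19801687 to 63623214. Reads without molecular identifiers are not independent molecules, so the limits given for a count of 0 (3 reads) cover counting error only.

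The summary over the U12-listed genes named in advance is not reported here.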

Results

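PolyA-selected RNA of mouse ES cells was counted at 219945 introns in 3 wild-type and 3 ZRSR2 knockout libraries. ZRSR2 is a protein of the minor (U12-dependent) spliceosome that recognises 3′ splice sites, and ZRSR1 is its paralog. The wild-type libraries held 19801687, 56340422 and 63623214 spliced reads (replicates 2, 3 and 5), and the knockout libraries 61904886, 31391313 and 37130068. Unspliced reads numbered between 700433 and 2140886 per library. The share of unspliced signal over all introns, the pooled MSI, was 1.74%, 1.75% and 1.65% in wild type and 1.56%, 1.89% and 1.72% in the knockout (exact permutation p = 1, two-sided). Each library counted as 1 sample. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 18 or more over genes), which does not tell separate cultures from technical repeats.

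The first comparison asked whether ZRSR2 transcripts were lost. The targeted gene Zrsr2 lies on chromosome X, and its 9 listed introns span 163936966 to 163958273 (mm10, minus strand). Spliced Zrsr2 reads were almost absent from the knockout at each of these introns. Wild-type libraries held 660, 2190 and 2129 such reads, and knockout libraries 33, 12 and 0. The level was 35.0 ± 4.26 CPM in wild type and 0.309 ± 0.280 CPM in the knockout (SD, n = 3 each), where the 0 in knockout replicate 5 allows up to 0.0836 CPM. The log2 change was −6.70 (SE 0.59, edgeR adjusted p = 0.0217). The adjusted p was above 0.05 without wild-type replicate 2 (0.145), wild-type replicate 5 (0.0869) or knockout replicate 3 (0.406), with log2 changes of −6.76, −6.75 and −6.78. The paralog Zrsr1 was not analysed here.

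**Figure D1:**
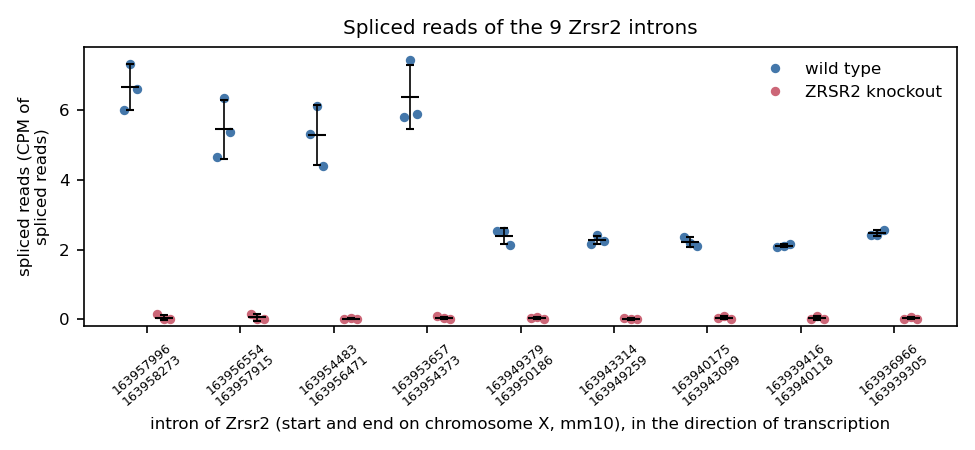
Spliced reads scaled to the total of spliced reads (vertical axis, CPM) at each of the 9 Zrsr2 introns, in the direction of transcription (horizontal axis, start and end on chromosome X). Points are libraries, bars are the mean and SD of 3. Knockout libraries lie near 0 at all 9 introns.

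The second comparison asked which genes changed in level. Besides Zrsr2, 2 genes fell in the knockout and none rose in edgeR, whereas DESeq2 also called genes in both directions. Mid1-ps1, a pseudogene copy of the ubiquitin ligase gene Mid1 at the end of chromosome Y, was at 293 ± 119 CPM in wild type and 9.996 ± 1.96 CPM in the knockout (log2 change −4.87, SE 0.35, edgeR adjusted p = 0.00997). Its reads cannot be told with certainty from those of Mid1 on chromosome X, which was at 14.7 CPM in wild type and 1.12 CPM in the knockout (log2 change −3.69, SE 0.40, edgeR adjusted p = 0.0527) and is named after its values were seen. Cep170, which encodes a centrosomal protein, was at 69.8 ± 14.7 CPM in wild type and 19.4 ± 3.22 CPM in the knockout (log2 change −1.85, SE 0.19, edgeR adjusted p = 0.0429). In these 3 genes every knockout library lay below every wild-type library.

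These 3 genes were the calls among 16922 tested. At an unadjusted p under 0.05 there were 1679 genes, 675 higher and 1004 lower, where chance alone gives 846. Groups did not overlap in 15.4% of genes, against 10% by chance. The number of calls depended on the test and on single libraries. DESeq2 called 218 genes (83 higher, 135 lower, the 3 included), and edgeR called 27 without wild-type replicate 3, 22 without knockout replicate 5, and 0 without knockout replicate 3. Of the 6 fits without 1 library, Cep170 lost its call in 4 (log2 change −1.97 to −1.67) and Mid1-ps1 in 1 (−5.17 to −4.64).

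The third comparison followed 17 gene lists. Genes of the major spliceosome that recognise the 3′ splice site and branch point were the 1 list that camera called. Of its 15 measured genes, 14 were higher in the knockout, with a median log2 change of 0.18 (camera adjusted p = 0.00282), and none passed alone. With an estimated correlation of 0.73 among its genes, the call was lost (adjusted p = 0.854 with an estimated correlation). U2af1, the major-spliceosome relative of ZRSR2, was at 460 ± 48.2 CPM in wild type and 562 ± 15.3 CPM in the knockout (log2 change 0.29, SE 0.10; named after its values were seen), and U2af2 at 739 ± 76.7 and 837 ± 53.1 CPM. Sf3b3 was at 634 ± 97.7 and 678 ± 62.0 CPM. The list of minor spliceosome proteins had a median log2 change of 0.13 over 13 genes, 10 of them higher (camera adjusted p = 0.284), with Zcrb1 at 60.2 ± 3.91 and 66.0 ± 3.22 CPM.

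Imprinted genes held the most single changes. Adjusted over the list alone, 5 of 21 measured genes rose and 2 fell, and adjusted over all genes tested none did in edgeR, whereas DESeq2 called all of them but Mirg. The noncoding RNA H19 was at 8.97 ± 3.19 CPM in wild type and 70.0 ± 35.9 CPM in the knockout (log2 change 2.97, SE 0.42). Rian (log2 change 0.59, SE 0.09), Meg3 (0.70, SE 0.15), Mirg (0.67, SE 0.20) and Dlk1 (0.75, SE 0.19), of 1 imprinted cluster on chromosome 12, were the other 4 that rose. Grb10, an adaptor of growth factor receptors, fell by 0.74 on the log2 scale (SE 0.16) and Igf2r, which clears IGF2, fell by 0.71 (SE 0.18). The list as a whole had a camera adjusted p of 0.0531, with a median log2 change of 0.14 (0.010 to 0.21 without single libraries). These members are named by their adjusted p over the list alone, after values were seen.

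In the naive pluripotency list, 2 of 20 genes fell when adjusted over the list alone: Tbx3 by 0.96 (SE 0.21) and Tdgf1 by 0.32 (SE 0.08) on the log2 scale, both chosen after values were seen. Pou5f1 was at 471 ± 128 CPM in wild type and 650 ± 50.8 CPM in the knockout, and Nanog at 93.7 ± 34.5 and 62.6 ± 7.77 CPM, and neither passed. The list had a median log2 change of −0.07 (camera adjusted p = 0.793). Formative and primed genes had a median of 0.21 (adjusted p = 0.620; −0.045 to 0.35 without single libraries), with Dnmt3b at 745 ± 388 and 1176 ± 96.8 CPM. Genes of the 2-cell-like state had a median of −0.78 (adjusted p = 0.0531), which was −0.24 without wild-type replicate 2 (0.580) and −1.24 without knockout replicate 2 (0.000415, and 0.880 with an estimated correlation). Among them Zscan4c, which shares sequence with its Zscan4 relatives, was at 23.6 ± 12.8 and 13.6 ± 7.46 CPM.

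The integrated stress response list had a median of −0.23, with 12 of 15 genes lower (camera adjusted p = 0.0531) and none passing alone. Without single libraries its median was −0.33 to −0.13. Camera called it without wild-type replicate 5 (adjusted p = 0.0285), knockout replicate 2 (0.0271) or knockout replicate 5 (0.0315). With an estimated correlation each of these calls was lost. Asparagine synthetase (Asns) was at 430 ± 56.2 CPM in wild type and 302 ± 63.6 CPM in the knockout. Median log2 changes were 0.09 for nonsense-mediated decay factors (camera adjusted p = 0.284), 0.12 for p53 targets (0.354), 0.12 for neural genes (0.369) and 0.05 for cell cycle E2F targets (0.568). They were −0.21 for mesoderm (0.568), −0.13 for endoderm (0.568), 0.73 for trophectoderm (0.605, with a median of −0.051 without knockout replicate 2) and −0.01 for methylation-sensitive germline genes (0.605). None of these lists had a member past the threshold in edgeR, over all genes or over the list alone. The p53 list had a median of 0.034 to 0.23 without single libraries. Camera called it only without knockout replicate 5, and there not with an estimated correlation. Fibroblast or feeder markers differed widely within both groups and had a median of 0.22 (0.620; −0.41 to 0.89 without single libraries, called only without knockout replicate 5, and there not with an estimated correlation). Col1a1 was at 116, 67.9 and 34.2 CPM in wild-type replicates 2, 3 and 5 and at 132, 86.0 and 17.7 CPM in the knockout ones. By fry, no list passed (smallest adjusted p = 0.116).

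The fourth comparison asked which introns were retained. Introns of Pola2 (a DNA polymerase alpha subunit), Larp7 (a 7SK RNA-binding protein), Taf2 (a TFIID subunit), Vps16 (a vesicle-tethering protein) and Polr2k (a subunit shared by RNA polymerases) held more unspliced reads in the knockout. These 5 genes are named after their values were seen. The Pola2 intron (chromosome 19, 5958876 to 5959032) had an MSI of 1.48% ± 0.395 in wild type and 9.18% ± 3.29 in the knockout (log2 odds 2.67, SE 0.35, edgeR adjusted p = 1.05e-09). In Larp7 (chromosome 3, 127545971 to 127546046) the MSI was 1.10% ± 0.212 and 4.49% ± 1.58 (log2 odds 1.98, edgeR adjusted p = 9.10e-05). A second Larp7 intron also rose (edgeR adjusted p = 0.0471), but its call held in only 1 of the 6 fits without 1 library. It was also lost with at least 10 unspliced reads (0.814). The Taf2 intron (chromosome 15, 55048742 to 55049394) went from 4.12% ± 1.28 to 21.0% ± 4.03, and the Vps16 intron (chromosome 2, 130440580 to 130440706) from 8.74% ± 2.18 to 25.7% ± 3.08. The Polr2k intron (chromosome 15, 36175477 to 36176753) went from 0.670% ± 0.193 to 2.13% ± 0.330 (SD, n = 3 each).

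**Figure D2:**
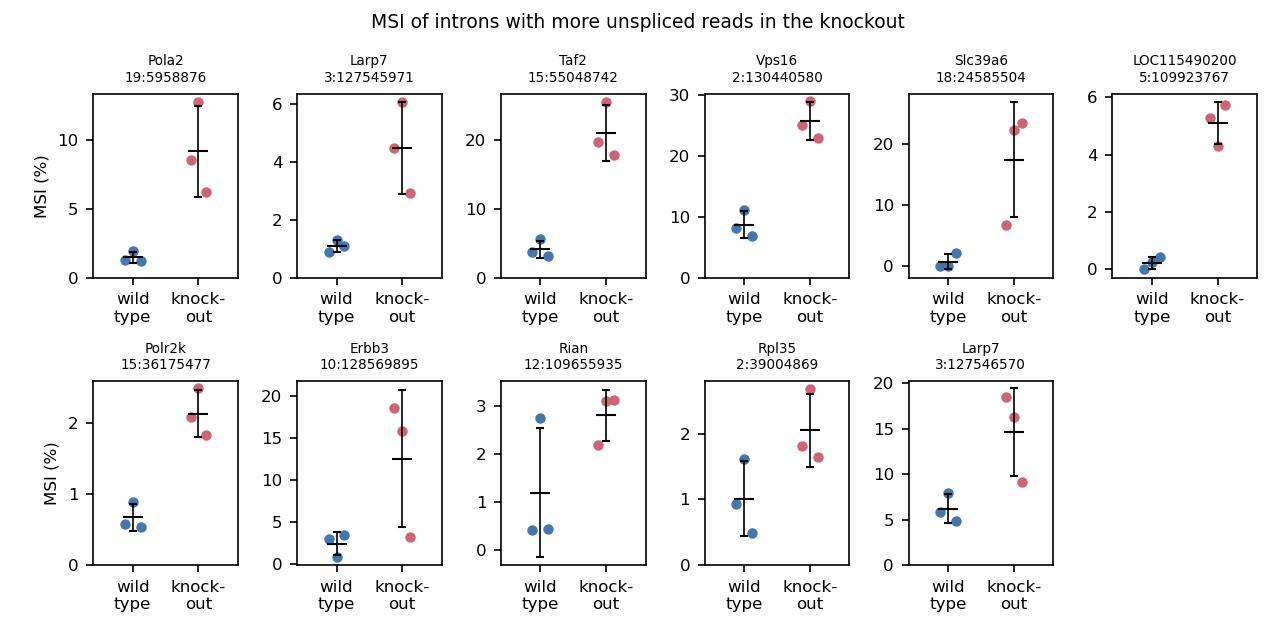
MSI in percent (vertical axes, each with its own scale) of the called introns with a higher ratio of unspliced to spliced reads in the knockout. Introns in the clusters on chromosomes 14, X and Y are left out. Titles give the gene and the intron's chromosome and start in mm10. Points are libraries, bars are the mean and SD of 3. Of these introns, those of Erbb3 and Rian have overlapping groups.

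By the fixed rule, the largest rises outside the U12 list were in Slc39a6 (a zinc transporter), the predicted gene LOC115490200, Plac9a, Anxa11 and Tmem254a. The Slc39a6 intron (chromosome 18, 24585504 to 24589746) had an MSI of 0.733% ± 1.27 in wild type and 17.4% ± 9.32 in the knockout. The LOC115490200 intron (chromosome 5, 109923767 to 109940425) had 0.220% ± 0.210 and 5.09% ± 0.725. Introns of Plac9a (log2 odds 3.67), Anxa11 (3.62) and Tmem254a (3.44) lie together on chromosome 14, beside copies of Plac9 and Tmem254, and how reads are divided among such copies was not determined here. The falls that the rule names were in Prr14 (log2 odds −4.61), Myl6b (−2.84) and the glycolysis gene Pfkp (−2.09). The next was in the predicted gene Gm13212 (−1.69), which is named after its values were seen. The Pfkp intron (chromosome 13, 6598012 to 6598738) went from 8.92% ± 1.63 to 2.38% ± 1.43.

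Of 95371 introns tested, 26 changed, 21 with a higher and 5 with a lower ratio of unspliced to spliced reads. Of these, 7 rises lie on chromosome 14 between 25877408 and 25984145, and 3 at the ends of chromosomes X and Y, where knockout reads were few. At the chromosome X intron starting at 170009907, unspliced reads also fell (4861, 12065 and 19307 in wild type, 522, 198 and 187 in the knockout). At the chromosome Y intron starting at 90785980 they fell from 3473, 10819 and 13257 to 475, 155 and 228. In Anxa11 spliced reads fell from 111, 365 and 387 to 27, 31 and 32, with few unspliced reads (3, 7 and 9 to 12, 4 and 9). At an unadjusted p under 0.05 there were 3951 introns, where chance gives 4769. The median tested intron had 23 unspliced and 1025 spliced reads over the 6 libraries. The edgeR fit took the spread of an intron from all introns together and not from its own libraries. In contrast, limma, which does not weigh introns by their reads, called 0 (4257 at an unadjusted p under 0.05). Pola2 and the first Larp7 intron passed in each of the 6 fits without 1 library, whereas Taf2 and Vps16 did not without wild-type replicate 5 (adjusted p = 0.391 and 0.462), Polr2k was lost in 3 of these fits, and Slc39a6 in 4 (log2 odds 3.64 to 7.91). Of the falls, 0 were called without wild-type replicate 2, 0 without wild-type replicate 5 and 0 with at least 10 unspliced reads, and the log2 odds of Myl6b was −1.16 without knockout replicate 5.

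The fifth comparison set the introns of genes known to hold a U12-type intron against all others. None of the 320 tested introns in 29 of the 30 listed genes was called in edgeR, and 26 of 95051 other introns were (0.0274%, Fisher's exact p = 1). At so low a share, 0 calls among 320 introns is the likely outcome whatever their class, so this test could not show fewer calls. The count of 0 allows a called share of up to 0.938% if introns of the same gene are independent. It sets no limit on changes too small to be called. At an unadjusted p under 0.05 there were 10 listed introns (5 higher, 5 lower), 3.12% against 4.15% of the others (Fisher's exact p = 0.480). Calls by limma were 0 in both classes. The listed intron with the smallest p was in Mapk14, a stress kinase gene (chromosome 17, 28728976 to 28737010), with an MSI of 2.36% ± 0.618 in wild type and 4.99% ± 0.898 in the knockout (log2 odds 1.17, SE 0.36, edgeR adjusted p = 0.392 over the list alone). Which introns are U12-type was not determined here, in listed or in other genes. Both classes may hold them, so the comparison does not tell whether the called introns are U12-type.

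Pooled over tested introns, the listed genes had an MSI of 2.11% ± 0.118 in wild type and 2.26% ± 0.236 in the knockout (SD, n = 3, exact permutation p = 0.5). All other genes had 1.67% ± 0.0587 and 1.69% ± 0.161 (exact permutation p = 1). The log2 ratio of the first to the second was 0.34 ± 0.04 in wild type and 0.42 ± 0.03 in the knockout. It was higher in every knockout library than in every wild-type one (exact permutation p = 0.1, the smallest that 3 against 3 can give). The margin was small, with 0.388 in knockout replicate 5 against 0.386 in wild-type replicate 3. The median log2 ratio of unspliced to spliced reads per library (0.5 added to both) overlapped between groups in both classes. For listed introns it was −4.70, −4.96 and −5.13 in wild type and −5.22, −4.63 and −5.05 in the knockout. For other introns it was −5.33, −5.45 and −5.51 in wild type and −5.65, −5.26 and −5.36 in the knockout. In expression, the 30 listed genes had a median log2 change of −0.02, 13 higher and 17 lower (camera adjusted p = 0.568), with Parp1 at 830 ± 35.4 CPM in wild type and 793 ± 24.0 CPM in the knockout.

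**Figure D3:**
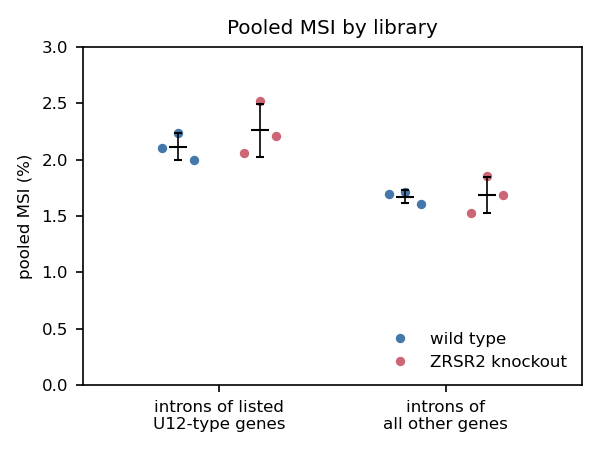
Pooled MSI in percent (vertical axis) of introns in the listed U12-type genes and in all other genes, by library. Points are libraries, bars are the mean and SD of 3. The groups overlap in both classes.

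The last comparison looked for use of other splice sites. Of 40 introns of listed genes with alternative junction reads, 0 changed in edgeR (2 at an unadjusted p under 0.05), and of 20106 introns of all genes 0 changed (429 at an unadjusted p under 0.05). Junctions that share a splice site were tested from both sides, so these tests hold 25 distinct comparisons in listed genes (1 at an unadjusted p under 0.05, in Srsf10, which is named after its values were seen) and 16849 in all genes (386). In all genes the counts at an unadjusted p under 0.05 are below what chance gives, and this test was not simulated. Its 0 calls therefore do not show that splice site use was unchanged. Usage of an intron relative to the others of its gene changed at 0 of 148974 introns (6537 at an unadjusted p under 0.05).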

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

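The check of covered intron length uses a deposited column that no comparison above draws on, and it was run on introns already chosen for their change. Of the 21 introns with a higher ratio of unspliced to spliced reads in the knockout, 5 had a higher covered fraction in every knockout library than in every wild-type library. Chance gives no fair yardstick here, since more unspliced reads by themselves raise coverage. These 5 were 2 introns of Plac9a and those of Cphx1, Slc39a6 and LOC115490200. The Slc39a6 intron was covered over a mean fraction of 0.409 in wild type and 0.594 in the knockout. The called introns of Pola2, Larp7 and Vps16 were fully covered in both groups and could not rise. The covered fraction of the 3 introns at the ends of chromosomes X and Y was lower in the knockout (1 to 0.788, 1 to 0.384 and 0.487 to 0.198). Over the 21 introns the median covered fraction was 0.784 and 0.900. Groups of 3 libraries were not tested for outlying samples.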

How the results depend on the processing

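Tests chosen after seeing the data were the robust prior, the minimum of 10 unspliced reads, the removal of 3 regions and the lists without single samples. Of 932 values under an alternative, 730 stayed the same, 152 were weaker, 24 were stronger and 26 changed sign. For a tested value, same means direction and side of the threshold were kept, weaker that the pass was lost, stronger that it was gained. For a count of calls, same means a similar count, and weaker or stronger a clearly smaller or larger one. The count of 3 genes stayed at 3 with DESeq2 size factors and with library size only. It was 7 with no filter, 218 with the DESeq2 Wald test (2641 adjusted p not given), and 0 to 27 without single samples (0 without knockout replicate 3, 1 without wild-type replicate 2 or 5, 22 without knockout replicate 5, 27 without wild-type replicate 3). The cause was not tested. The targeted gene Zrsr2 kept a log2 change of −7.57 to −6.19 without single samples.

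The labels give same-numbered samples only a number in common. Over genes, deviations of same-numbered samples correlated at 0.063, 0.069 and 0.016, and wild-type replicates 2 and 3 but not 5 correlated best with their own number. Yet of 12 measured fibroblast or feeder markers, some fell in the order of replicates 2, 3 and 5 in both groups. These were Col1a1, Col1a2, Col3a1, Col5a2, Postn and S100a4, whereas Thy1, Dcn, Acta2, Pdgfrb, Fbn1 and Mmp2 did not follow it. With the replicate block the SE of Col1a1 went from 0.65 to 0.24 and that of Col1a2 from 0.82 to 0.35. With a replicate block 8 genes (2 higher, 6 lower), 23 introns and 2 gene lists were called, the second being the 2-cell-like list (adjusted p = 1.07e-05, and 0.761 with an estimated correlation).

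The call of 1 list became 0 with the estimated correlation and with fry, and 1 to 5 without single samples (5 without wild-type replicate 5, 4 without knockout replicate 2, 5 without knockout replicate 5), and all of these calls were lost with an estimated correlation. Without single samples the median log2 change turned sign in the trophectoderm (−0.051 to 1.12), mesoderm (−0.54 to 0.033), endoderm (−0.26 to 0.074), neural (−0.049 to 0.26), E2F (−0.0066 to 0.11), germline (−0.25 to 0.062), fibroblast and formative lists. The 26 introns outside the U12 list became 0 with limma and 0 with the other junctions as reference. They became 9 with at least 10 unspliced reads, 11 without the 3 regions, 13 at an adjusted p under 0.01, and 7 to 25 without single samples (7 without wild-type replicate 5, 15 without wild-type replicate 2, 16 without knockout replicate 3). Only rises were left with at least 10 unspliced reads, at an adjusted p under 0.01 and without wild-type replicate 2 or 5. With at least 10 unspliced reads the Polr2k (adjusted p = 0.202) and Slc39a6 (0.246) introns were lost. In the limma, block and read-minimum fits all of the 26 that were tested kept their sign. With the other junctions as reference 6 of 24 had the same sign, but that fit measures the use of the spliced junction and not retention. Retention lowers spliced reads, so it would give the opposite sign in that fit. The listed introns stayed at 0 in every setting run. Alternative junctions of all genes went from 0 to 1 without wild-type replicate 2. The median log2 change of the listed genes was −0.065 to 0.017 without single samples, above 0 without knockout replicate 2.

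Sign changes fell on values that passed no threshold. With library size only the log2 changes were −0.018 (Dppa5a), −0.018 (Upf1), −0.018 (Sycp1) and −0.014 (Mcm7), and with the replicate block −0.064 (Col1a2) and −0.13 (Col1a1). Without single samples they ranged from −0.010 to 0.21 (Sf3b3), −0.071 to 0.16 (Dppa5a), −0.27 to 0.16 (Tbx6), −0.30 to 0.073 (Col4a1), −0.053 to 0.13 (Pax6), −0.051 to 1.29 (Krt8), −0.40 to 1.06 (Col1a2), −0.48 to 0.63 (Col1a1), −0.0044 to 0.042 (Upf1), −0.18 to 0.071 (Ddx4), −0.31 to 0.37 (Sycp1) and −0.026 to 0.091 (Mcm7). The cause was not tested.

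Motif-based definitions of U12-type introns were not run, since no genome sequence was used here, and the alternatives for normalized values do not apply to counts. Of the tested introns, 4890 had no unspliced read in any library.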

Other observations

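Except for the count of DESeq2 calls in other splits, all tests in this part were chosen after the results they bear on were seen. A list of 30 genes that respond to interferon was written after values were seen. Of these, 25 were measured and 25 of 25 had a higher mean in the knockout (median log2 change 1.87), but the list did not pass with an estimated correlation of 0.61 (camera p = 0.108) or by fry (p = 0.0642). No member passed in edgeR over all genes, and DESeq2 called 11 of them. The ubiquitin-like Isg15 was at 0.149, 0.219 and 0.168 CPM in wild-type replicates 2, 3 and 5 and at 5.82, 2.05 and 0.251 CPM in the knockout ones. Knockout replicate 5 lay close to wild type, and the mean log2 CPM of the list was 1.78, 1.54 and 1.55 in wild type and 4.35, 3.89 and 1.96 in the knockout. Without single libraries the camera p was 0.166 to 0.253, except for 0.00520 without knockout replicate 5, the library that goes against the pattern, and the median log2 change was 1.10 to 2.38. In the knockout the fibroblast or feeder marker Col1a1 followed the same order (132, 86.0 and 17.7 CPM), and it was at 116, 67.9 and 34.2 CPM in wild type. Whether these are linked was not tested.

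Of 24 genes of the hypoxia response and glycolysis, a list also written after values were seen, 23 had a lower mean in the knockout (median log2 change −0.88). The list did not pass by camera with an estimated correlation of 0.44 (p = 0.0838), and its fry p was 0.0341. Without single libraries the camera p was 0.108 to 0.152, except for 0.0256 without wild-type replicate 3, and the median was −1.13 to −0.62. Of the 24, Ddit4 is also in the integrated stress response list. No member passed in edgeR over all genes, and DESeq2 called 12 of them lower. The mitophagy receptor Bnip3 was at 64.3, 26.5 and 87.0 CPM in wild-type replicates 2, 3 and 5 and at 16.6, 11.9 and 10.9 CPM in the knockout. The glucose transporter Slc2a1 was at 600, 431 and 827 CPM in wild type and at 391, 301 and 275 CPM in the knockout. A spread between cultures that is not tied to genotype cannot be told apart from an effect of the knockout, because wild-type replicate 3 lay near the knockout. The range of the wild-type list means was 0.977 of the gap between the group means, with no overlap. ZRSR2 loss itself stays open, since each genotype is represented by 3 libraries of unstated origin.

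Mid1 and Mid1-ps1, at the pseudoautosomal ends of chromosomes X and Y, had far lower means in the knockout. Loss of the Y chromosome is argued against by 5 Y genes outside that end (Ddx3y, Eif2s3y, Kdm5d, Uty and Uba1y). Their median log2 change was 0.34, with values from 0.25 to 0.90. DESeq2 called Eif2s3y and Kdm5d higher (adjusted p = 3.88e-05 and 0.00150), and edgeR called neither. A deletion reaching from Zrsr2 to the end of chromosome X is argued against too, because 15 genes between Zrsr2 and Mid1 had a median of −0.034, with values from −0.26 to 0.49. Reads moving between the X and Y copies do not account for it, since the sum of both fell by 4.78 on the log2 scale (SE 0.34). Spliced reads were also far fewer in the knockout at called introns of these ends that have no gene name (replicates 2, 3 and 5). On chromosome Y (90785980 to 90793295) they numbered 10160, 44531 and 52311 in wild type and 657, 200 and 211 in the knockout. On chromosome X (170009907 to 170010673) they numbered 277, 1681 and 3568 in wild type and 7, 2 and 1 in the knockout. A change limited to the pseudoautosomal end in the knockout line and an effect of ZRSR2 loss both stay open and were not tested.

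On chromosome 14, copies of Plac9, Tmem254, Cphx and Duxbl moved apart. The b copies Plac9b and Tmem254b had log2 changes of 1.64 (SE 0.20) and 1.53 (SE 0.22), whereas Cphx1 and Duxbl1 had −0.74 (SE 0.15) and −0.61 (SE 0.15). None of these passed the threshold in edgeR, whereas DESeq2 called each (adjusted p = 5.12e-10, 1.33e-07, 0.00339 and 0.0237). Reads moved between near-identical copies are a candidate explanation for Plac9, Cphx and Duxbl, whose family sums had a median log2 change of 0.11. For Tmem254 this is argued against as the whole cause, since its family sum changed by 0.62 (SE 0.16), from 61.4 ± 11.2 to 94.3 ± 14.2 CPM. Why reads would be placed differently in the knockout was not tested, and a sequence or copy-number difference of the knockout line and an effect of ZRSR2 loss stay open.

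The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For edgeR genes, 1 of the 10 splits, the real one, gave as many as 3 calls, and the highest of the others gave 0. For retained introns, 2 of 10 gave as many as the real 26, and the highest other gave 44. For DESeq2 genes, 2 of 10 gave as many as the real 218, and the highest other gave 602. The higher counts of introns and of DESeq2 genes came from the same split, wild-type replicates 2 and 5 with knockout replicate 2 against the rest. Whether a structure of the samples that the labels do not give lies behind this was not tested. The intron and DESeq2 counts are to be read with care.

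In genes with a raised intron, the other 17 tested Pola2 introns had a median log2 odds of −0.16 (1 of them higher at an unadjusted p under 0.05), the other 10 Larp7 introns −0.10 (2 higher) and the other 24 Taf2 introns −0.22 (1 higher). The other 22 Vps16 introns had 0.453 (4 higher), the other 25 Erbb3 introns 0.455 (1 higher), and the 1 other LOC115490200 intron 1.76 (0 higher). The log2 change of spliced reads was 0.09 (Pola2), 0.39 (Larp7), 0.13 (Taf2), −0.24 (Vps16), −0.21 (Erbb3), −0.49 (LOC115490200) and −0.67 (Slc39a6), none past the threshold in edgeR, and DESeq2 called Slc39a6 (adjusted p = 0.00893). At all 18 listed Cep170 introns every knockout library lay below every wild-type library. The ratio of the knockout mean to the wild-type mean was between 0.155 and 0.402 at 17 of them, and 0.841 at the junction from 176793650 to 176813895 on chromosome 1, with 1.502 ± 0.0193 CPM in wild type and 1.26 ± 0.167 CPM in the knockout. Knockout replicate 2 kept 33 spliced Zrsr2 reads and knockout replicate 3 kept 12.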
